A study of Homo sapiens with 4 samples.

How the data were processed

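RNA from exosomes of MRC5 mono-culture (2 libraries) and of MRC5 and 1833 co-culture (2 libraries) was sequenced. Per the labels' protocols, vesicles came from conditioned medium by ultracentrifugation or by polyethylene glycol precipitation, without saying which library had which, RNA was taken with TRIzol, and directional libraries were made without fragmenting the RNA. The deposited table holds raw read counts per feature, which the authors did not normalise as far as its whole numbers and differing totals show. Per the submitters' processing notes, the tools were CASAVA, cutadapt 1.9, Bowtie2 2.2.4, STAR 2.4.0k, SAMtools and Subread 1.4.6, and the builds were GRCm38, mm10 and GRCh38, with no role given. Strand setting, filters and the treatment of reads that map to several places are not given in the sources used here, so reads shared by near-identical copies could be lost or assigned to 1 copy.

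The table has 3125559 rows, made of 12 reference sequences (rRNA, its spacers and 7SL RNA), 66203 Ensembl genes and 3059344 repeat loci of 846 names. No repeat locus overlaps a gene on the same strand. RN7SL1 was read from its reference sequence, since the annotated gene row of the same RNA held 0 reads. Of the Ensembl IDs, 57055 were in GENCODE 29 and 95.1% of these had identical coordinates, so positions are given on GRCh38. Symbols came from the table or, for 6599 rows without one, from reference tables.

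Total counts ran from 2062340 to 4146272 per library, and intervals and floors cover counting error only. Shares of RNA classes were computed over all assigned counts and given as means with SD. Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment, threshold 0.05), with the culture as the only term. TMM-scaled CPM (counts scaled to a common library size, which for RN7SL1 can exceed the assigned total) use library sizes multiplied by TMM factors, which were 2.51 and 3.54 in mono-culture and 0.330 and 0.341 in co-culture. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1). Counts were summed over loci for repeat families with at least 10 counts in 2 libraries and tested in the same way. A gene with 0 counts in a group was given a bound from 3 counts over the group, and one with 1 to 3 counts a rate ratio with an exact 95% interval. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for tables.

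Before the data were examined, the samples, the tests, 25 gene lists, most alternatives and the rule for naming genes were fixed. The rule took, among genes past the threshold whose groups do not overlap, the 10 largest folds in each direction at a mean of 10 CPM or more (filled from 1 or more), RN7SL1, RN7SL2 and RN7SL3, up to 4 called members of each list by adjusted p or otherwise the 2 most abundant, the 5 most abundant genes of each group, and the 5 repeat families with most counts plus 5 by adjusted p; the text gives part of these. Alternatives were DESeq2 size factors, library size alone, the replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, other count filters, scaling without rRNA, 7SL and polymerase III genes, 2 further list tests, and 2 further ways to sum or scale repeats. Scaling to rRNA, to repeat counts and to all assigned counts was added after the data were seen. Library size alone means the reads summed over the tested genes, or, for repeat families, over the genes and families that passed the filter. Pseudocounts do not apply to counts.

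The steps were tested on simulated counts for the comparison of co-culture with mono-culture. Over 7798 genes, 14% of genes changed 2-fold were recovered, 82% at 4-fold, 100% at 8-fold higher and 18% at 8-fold lower, with 10 false calls among 117. Over 765 repeat families, 47 of 50 changed 2-fold were recovered with 9 false calls among 56. The ribosomal protein list, raised 2-fold in simulated genes that varied independently, was recovered by camera (adjusted p = 6.75e-23) but not by fry (adjusted p = 0.0749). Neither test called any of the 14 other lists. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom 3.13 in mono-culture and 32.8 in co-culture), so none was counted as a duplicate.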

Results

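The series measured RNA carried by exosomes, small vesicles that cells release into their medium. Total RNA was sequenced from vesicles of MRC5 cells, a line of human fetal lung fibroblasts, grown alone (mono-culture, 2 libraries), and of MRC5 cells grown in an equal mixture with 1833 cells, a bone-tropic derivative of the breast cancer line MDA-MB-231 (co-culture, 2 libraries). The title of the series places the comparison in work on RIG-I, a sensor of viral RNA, and on endogenous RNA that this sensor can meet in exosomes. The count table assigned 2062406 and 2062340 reads in the mono-culture libraries, and 4146272 and 2803597 in the co-culture libraries. Of these, annotated Ensembl genes took 187291, 211858, 124586 and 83111 reads in the same order, so that single mRNAs were measured with few reads. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, and no such test was used to call a difference.

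The first question was which RNA classes the vesicles of each culture held. 7SL RNA, the RNA scaffold of the signal recognition particle that guides secreted and membrane proteins to the endoplasmic reticulum, made up 2.84% ± 0.594 (SD, n = 2) of assigned reads in mono-culture and 60.1% ± 2.49 (SD, n = 2) in co-culture. Repeat loci other than rRNA and tRNA copies held 53.5% ± 5.98 (SD, n = 2) in mono-culture and 13.4% ± 0.143 (SD, n = 2) in co-culture. The 28S rRNA of the large ribosomal subunit held 19.7% ± 3.69 and 10.6% ± 0.564 (SD, n = 2 each), and the 18S rRNA of the small subunit held 9.97% ± 2.29 and 11.4% ± 1.59 (SD, n = 2 each). Protein-coding genes held 6.01% ± 0.893 in mono-culture and 1.49% ± 0.0116 in co-culture (SD, n = 2 each). Shares sum to a whole, so a class that fills most of a library lowers the share of each other class.

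**Figure D1:**
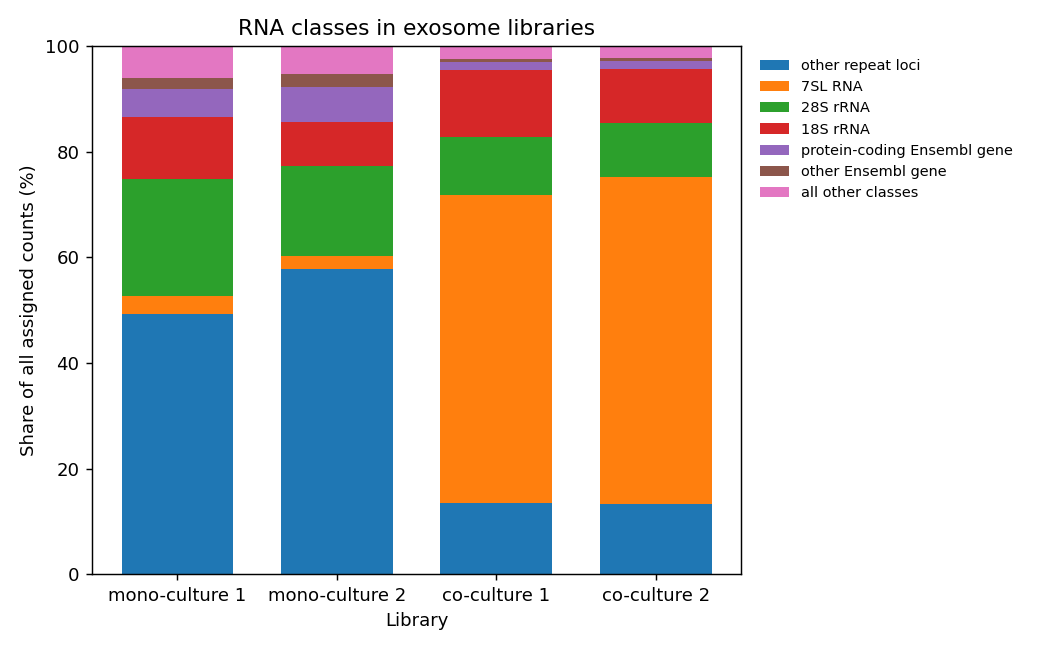
Stacked bars give the share of all assigned counts (%, vertical axis) taken by each RNA class in each of the 4 libraries (horizontal axis), without error bars because each bar is 1 library. 7SL RNA averages 2.84% in the mono-culture bars and 60.1% in the co-culture bars.

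Ratios of RNAs within a library do not depend on scaling. They can still depend on the length and integrity of each RNA, since the RNA was not fragmented, and this was not examined. The ratio of 7SL to 28S reads was 0.144 ± 0.00316 in mono-culture and 5.69 ± 0.538 in co-culture (SD, n = 2 each), a 39.5-fold difference, and the ratio of 7SL to 18S reads differed 18.6-fold. The 18S to 28S ratio was 0.504 ± 0.0218 in mono-culture and 1.08 ± 0.0932 in co-culture (SD, n = 2 each). The 5.8S rRNA, which pairs with 28S in the ribosome, had a ratio to 28S of 0.0341 ± 0.00231 and 0.0173 ± 0.00368 (SD, n = 2 each). For the 5S rRNA, transcribed by RNA polymerase III, the ratio to 28S was 0.0504 ± 0.00367 and 0.0470 ± 0.00355 (SD, n = 2 each), a difference within the spread of the replicates. These ratios were not tested.

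The second comparison asked whether RN7SL1, the endogenous RNA at the centre of the study, was more abundant in co-culture vesicles. RN7SL1 rose in co-culture: its reference sequence received 67316 and 49980 reads in the mono-culture libraries and 2419703 and 1734942 in the co-culture libraries. As a share of all assigned reads this was 28437 ± 5943 CPM against 601206 ± 24920 (SD, n = 2 each), 21.1-fold. The log2 fold change after TMM scaling was 6.48 ± 0.60 (SE), with an adjusted p of 1.14e-10 in edgeR's quasi-likelihood test. RN7SL2 (chromosome 14, 49862550 to 49862849, minus strand, GRCh38) rose 88.1-fold on the TMM scale, with 22 and 25 reads in mono-culture and 1077 and 593 in co-culture. RN7SL3 (chromosome 14, 49853616 to 49853914, minus strand) rose from 3 and 5 reads to 256 and 240. These genes are near-identical to RN7SL1, so reads between them are uncertain. The sum of the 3 rose from 28450 ± 5941 to 601515 ± 24903 CPM (SD, n = 2 each). Nearly all reads of this sum were on the RN7SL1 reference, so it gives no separate check. The size depends on the scaling: library size alone, here the reads summed over tested genes without repeat loci, gave a log2 fold change of 3.36. The call was lost in edgeR without mono-culture replicate 1 (adjusted p = 0.128), without co-culture replicate 1 (adjusted p = 0.698) and without co-culture replicate 2 (adjusted p = 0.984), with log2 fold changes of 6.44 to 6.77, and kept without mono-culture replicate 2 (log2 fold change 6.05, adjusted p = 2.62e-75). The cause of this difference was not tested.

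The third comparison covered all annotated genes. Of 7798 genes tested, 37 rose and 2 fell in co-culture (edgeR's quasi-likelihood test, adjusted p under 0.05), and most of those that rose were short structured noncoding RNAs. They were the 7SL reference, 9 annotated 7SL copies, 13 genes or copies of U1, the small nuclear RNA that recognises the start of introns, 3 further snRNA genes, 5 snoRNAs, the 18S rRNA, 3 protein-coding genes and 2 other genes. On an unadjusted p under 0.05, 216 genes were higher and 265 lower. The groups did not overlap for 37.5% of genes, where chance gives 33.3%. The count depended on single libraries: edgeR called 0 genes higher and 0 lower without mono-culture replicate 1, 35 and 1 without mono-culture replicate 2, 19 and 0 without co-culture replicate 1, and 13 and 0 without co-culture replicate 2.

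Fold changes among 7SL copies were the largest. The rate ratios and folds given here are on the TMM scale, and their size depends on it. With library size alone the log2 fold change was 7.09 for RN7SL674P, 5.47 for RN7SL128P, 1.80 for RN7SL5P and 1.74 for RN7SL151P. RN7SL674P (chromosome 2, 11584773 to 11585047) had 2 and 0 reads in mono-culture and 547 and 434 in co-culture, a rate ratio of 1250 with an exact 95% counting interval of 345 to 10337. RN7SL128P had 2 and 0 reads against 222 and 110 (rate ratio 423, interval 116 to 3508), and RN7SL767P had 2 and 1 against 52 and 46 (rate ratio 83.3, interval 27.7 to 411). These folds move with single mono-culture libraries: without mono-culture replicate 1 or 2 the log2 fold change of RN7SL674P was 12.58 or 8.92 against 10.06, and that of RN7SL128P 10.96 or 7.30 against 8.45, and without mono-culture replicate 2 that of RN7SL767P was 5.60 against 6.23. RN7SL396P rose 127-fold, RN7SL4P 68.4-fold, RN7SL5P 30.2-fold and RN7SL151P 28.5-fold (log2 fold change 4.84, and 4.21 or 5.75 without mono-culture replicate 1 or 2). Copies hold sequence in common with RN7SL1, so their counts may be reads of RN7SL1 and are uncertain as separate transcripts.

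Among other small RNAs, RNVU1-18, a variant U1 gene, rose from 2.22 ± 1.00 to 22.8 ± 11.5 TMM-scaled CPM (SD, n = 2 each; adjusted p = 2.44e-06 in edgeR). RNU1-1, a U1 gene, rose from 543 ± 123 to 2124 ± 328 (adjusted p = 0.0152 in edgeR), and RNU1-3, another, from 43.5 ± 18.9 to 232 ± 35.8 (adjusted p = 0.00015 in edgeR). RNU2-1, a U2 gene, whose RNA pairs with the intron branch point, rose from 19.4 ± 4.50 to 80.9 ± 8.68 (adjusted p = 0.000303 in edgeR). SNORD3A, a U3 snoRNA that takes part in pre-rRNA processing, rose 6.97-fold, and SNORD3C, a further U3 gene, 7.07-fold. SNORA54 rose 7.89-fold and SNORA65 7.02-fold. The 18S rRNA rose 4.86-fold (adjusted p = 0.00834 in edgeR) and RNA5-8S5, an annotated 5.8S gene with few reads, 3.72-fold, while the 5.8S reference sequence, with 5487 and 6475 TMM-scaled CPM, had a log2 fold change of 0.24 (adjusted p = 0.969 in edgeR). These rises are relative to the median gene: library size alone moves all genes down alike, so that a gene with a smaller log2 fold change than this shift, as all of these but RNVU1-18 (0.28), must turn negative. Scaled to rRNA, RNVU1-18 (log2 fold change 1.71, adjusted p = 0.0208), SNORD3A (1.15, 0.0218) and RNU1-3 (0.79, 0.0340) kept their calls (18S is itself part of this scaling), and scaled to all assigned counts RNVU1-18 alone did (1.33, adjusted p = 0.0287). At log2 fold changes near those of the main fit (2.28 for 18S and 1.97 for RNU1-1), 18S and RNU1-1 lost their calls without a count filter (1.88, adjusted p = 0.910, and 1.57, 0.421) and scaled to repeat counts (2.16, 0.0518, and 1.85, 0.0991). Without mono-culture replicate 2 the log2 fold change of SNORA65 went from 2.81 to 2.15, that of RNVU1-18 from 3.41 to 2.81 and that of SNORD3C from 2.82 to 2.23. Without co-culture replicate 2, at log2 fold changes of 1.95 to 2.96, the calls of SNORD3A (adjusted p = 0.277), SNORD3C (0.203), RNU1-1, RNU1-3, RNU2-1 and 18S (0.984 each) and RNA5-8S5 (0.912) were lost. Without co-culture replicate 1, at log2 fold changes of 1.55 to 2.19, those of RNU1-3 (0.260), RNU1-1 (0.958), 18S (0.983) and RNA5-8S5 (0.551) were lost, and that of RNA5-8S5 also without mono-culture replicate 2 (1.33, adjusted p = 0.445).

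The genes named above followed the rule fixed in advance, except the 5.8S reference sequence. The 3 protein-coding genes that rose were chosen for naming after their values were seen. VPS13A, a lipid transfer protein, had 19 and 31 reads in mono-culture and 259 and 159 in co-culture, 21.1-fold higher. GAPDH, a glycolytic enzyme, had 18 and 21 against 107 and 52, 10.1-fold higher, and RPH3A, which acts in vesicle exocytosis, had 6 and 9 against 13 and 13. With library size alone VPS13A stayed higher (log2 fold change 1.21), GAPDH lost its call (0.17, adjusted p = 0.702) and RPH3A turned negative (-0.99). RPH3A also lost its call without a count filter (1.75, adjusted p = 0.350), without mono-culture replicate 2 (2.19, 0.151), without co-culture replicate 2 (1.92, 0.984) and scaled to rRNA (0.47, 0.495). Without mono-culture replicate 1, where edgeR called no gene, the log2 fold changes were 4.11, 3.26 and 1.9, against 4.40, 3.33 and 2.12 with all libraries. PRAMEF1 (10 and 11 reads) and FAM186B (8 and 13 reads) had 0 reads in both co-culture libraries. Against a floor of 3 counts over the group each was at least 2.75-fold lower. Both calls were lost in edgeR with the replicate block (log2 fold change -5.90, adjusted p = 0.0848 for PRAMEF1, and -5.83, 0.0975 for FAM186B, against -5.89 each). They were also lost in edgeR without a count filter (-6.01, 0.139 each) and with limma-voom (-3.09, 0.313 and -3.06, 0.336). DESeq2 gave neither gene an adjusted p. With library size alone, which moved the median log2 fold change of all genes from -0.04 to -3.14, 11 genes were higher and 7769 lower.

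**Figure D2:**
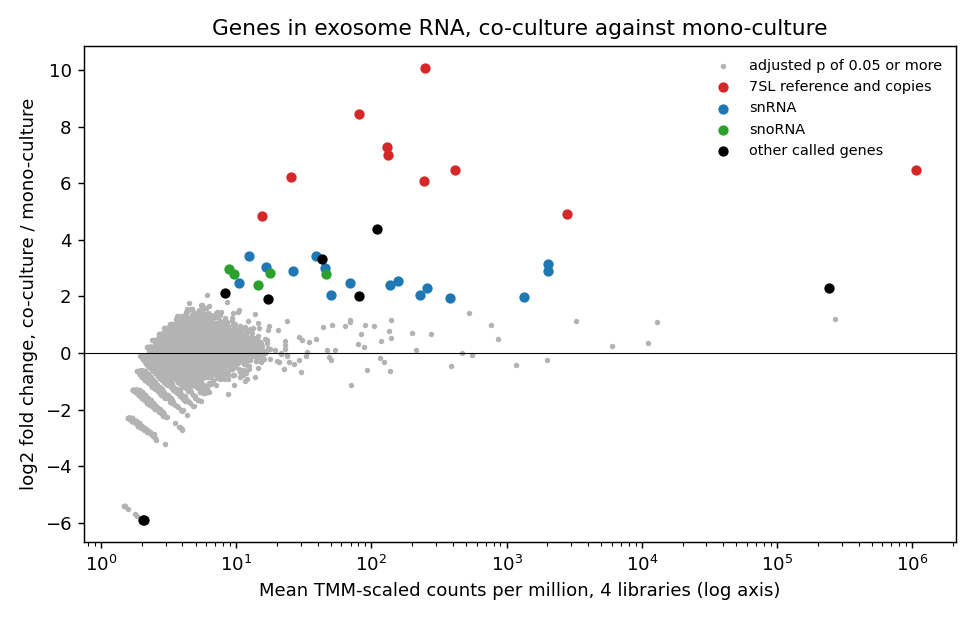
Each point is 1 of 7798 genes, with its mean TMM-scaled CPM over the 4 libraries (horizontal log axis) against the log2 fold change of co-culture over mono-culture (vertical axis). Coloured points passed an adjusted p of 0.05; the 7SL reference stands at 6.48 on the right, and with library size alone its value was 3.36.

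The fourth comparison asked how groups of genes fixed in advance behaved. Of 22 lists tested with camera, 6 were higher and 1 was lower in co-culture, and with an estimated correlation no list was called, the lowest adjusted p being 0.162. At an unadjusted p under 0.05 the estimated correlation gave 2 lists, and fry called 1. On simulated counts fry missed a list raised 2-fold (adjusted p = 0.0749 in fry), so a list that it did not call may still have changed. Among 7SL pseudogenes, 7 of 9 members tested rose (7 adjusted over the list alone), with a camera adjusted p of 2.61e-27 and an adjusted p of 0.162 with an estimated correlation. These 9 came from 683 annotated loci. RN7SL674P and RN7SL128P, with 2 and 0 mono-culture reads, and RN7SL767P, with 2 and 1, could pass the count filter only through co-culture libraries. So could RN7SL151P, with 1 and 4 mono-culture reads. The filter thus favoured a rise of this list. All 5 snoRNAs tested, of 553 annotated, rose (5 adjusted over the list alone, camera adjusted p = 5.06e-13, adjusted p = 0.472 with an estimated correlation). SNORA54 (4 and 6 mono-culture reads), SNORA65 (8 and 4) and SNORA73B (19 and 4) could not pass the count filter on mono-culture reads alone. For these the filter favoured a rise too, while SNORD3A (36 and 22) and SNORD3C (14 and 8) passed in mono-culture. Among spliceosomal snRNAs, 4 of 10 rose (6 adjusted over the list alone; camera adjusted p = 1.85e-09, adjusted p = 0.503 with an estimated correlation). Of the RNA polymerase III transcripts, 3 of 12 rose (7 adjusted over the list alone; camera adjusted p = 7.88e-09, adjusted p = 0.503 with an estimated correlation), and these were RN7SL1, RN7SL2 and RN7SL3. Of the cytosolic rRNAs, 2 of 4 rose (3 adjusted over the list alone; camera adjusted p = 1.83e-05, adjusted p = 0.503 with an estimated correlation).

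Mitochondrially encoded rRNAs and mRNAs were called higher as a list (camera adjusted p = 0.0438, adjusted p = 0.503 with an estimated correlation), but none of the 5 members passed on its own (0 adjusted over the list alone). This call was lost in each fit that left out 1 library (adjusted p from 0.0762 to 0.377 in camera), with library size alone (0.724) and with the replicate block (0.0733). The 12S rRNA had 30.03 ± 3.04 TMM-scaled CPM in mono-culture and 57.7 ± 5.06 in co-culture, and the 16S rRNA had 99.9 ± 28.9 and 135 ± 21.4 (SD, n = 2 each). Y RNA pseudogenes were called lower as a list (camera adjusted p = 0.0298, adjusted p = 0.762 with an estimated correlation), and none of the 28 members passed (0 adjusted over the list alone). The call of this list was lost without mono-culture replicate 1 and without either co-culture library, and the list changed direction without a count filter. RNY3P1 had 567 ± 156 and 534 ± 97.1 (SD, n = 2 each).

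None of the remaining 15 lists was called, and 0 of their members passed over all genes or adjusted over the list alone; the lowest camera adjusted p was 0.397. Interferon-stimulated genes, which RIG-I signalling induces in cells, had 17 members tested and a camera adjusted p of 0.474. Their most abundant members were PARP14, with 6.21 ± 1.86 TMM-scaled CPM in mono-culture and 4.60 ± 0.429 in co-culture, and MX2, with 6.02 ± 2.12 and 6.07 ± 0.0806 (SD, n = 2 each). Over all 54 genes of this list, reads per kb averaged 1.185 in mono-culture and 0.463 in co-culture. All autosomal repeats had 1.16 and 0.491. Most reads of this list may thus be background, so a change in these mRNAs could have gone unseen. The fibroblast and epithelial lists averaged above the repeats in both cultures, but part of their reads may be background too. Fibroblast markers had a camera adjusted p of 0.397. COL1A1 had 9.35 ± 0.964 and 12.5 ± 3.11, and COL6A3 16.6 ± 5.79 and 14.2 ± 0.679 (SD, n = 2 each). Epithelial and basal breast cancer markers had a camera adjusted p of 0.995, and EGFR had 6.80 ± 1.62 and 7.79 ± 2.35 (SD, n = 2 each). The other lists not called were genes of bone-tropic derivatives, NOTCH and MYC, polymerase III subunits, vesicle marker mRNAs, nuclear lncRNAs, and YAP and TGF-beta targets. They also covered cell cycle genes, inflammation, serum and blood, endothelium, ribosomal proteins and microRNA genes. The microRNA members tested were mostly host genes, such as MIR100HG. Of 3 further lists, signal recognition particle proteins had 2 members tested, histones 0 and mitochondrial tRNAs 1, too few for a test.

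The fifth comparison covered repeats. SSU-rRNA_Hsa, the genomic copies of 18S rRNA, was the 1 repeat family of 765 that rose (log2 fold change 2.09 ± 0.23 SE, adjusted p = 0.0183 in edgeR), from 949 ± 340 to 4023 ± 362 TMM-scaled CPM (SD, n = 2 each), and 0 fell. At an unadjusted p under 0.05, 26 families were higher and 22 lower in edgeR, and DESeq2 called 2 higher and 2 lower. Reads of the copies cannot be separated from those of 18S rRNA. None of 46 Alu families passed. AluJb, the family with most reads, had 8253 ± 685 and 9228 ± 597, and AluSx1 had 7944 ± 1784 and 8812 ± 413 (SD, n = 2 each). The LINE family L2a had 7309 ± 811 and 7605 ± 807, and the SINE family MIRb 7198 ± 385 and 6906 ± 103 (SD, n = 2 each). Of 24 tRNA families 22 had a negative fold change and none passed; tRNA-Gln-CAA had 56.8 ± 1.05 and 27.3 ± 3.96 (SD, n = 2 each). Leaving out single libraries gave 2 to 27 families higher and 2 to 24 lower, the most without mono-culture replicate 1. Counts of families moved by more than 1.5 times in most alternatives, and SSU-rRNA_Hsa lost its call with library sizes from repeats alone (log2 fold change 2.03, adjusted p of 0.08) and with the replicate block (2.13, adjusted p = 0.148) at nearly the same fold, and its log2 fold change was -0.028 with library size alone.

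**Figure D3:**
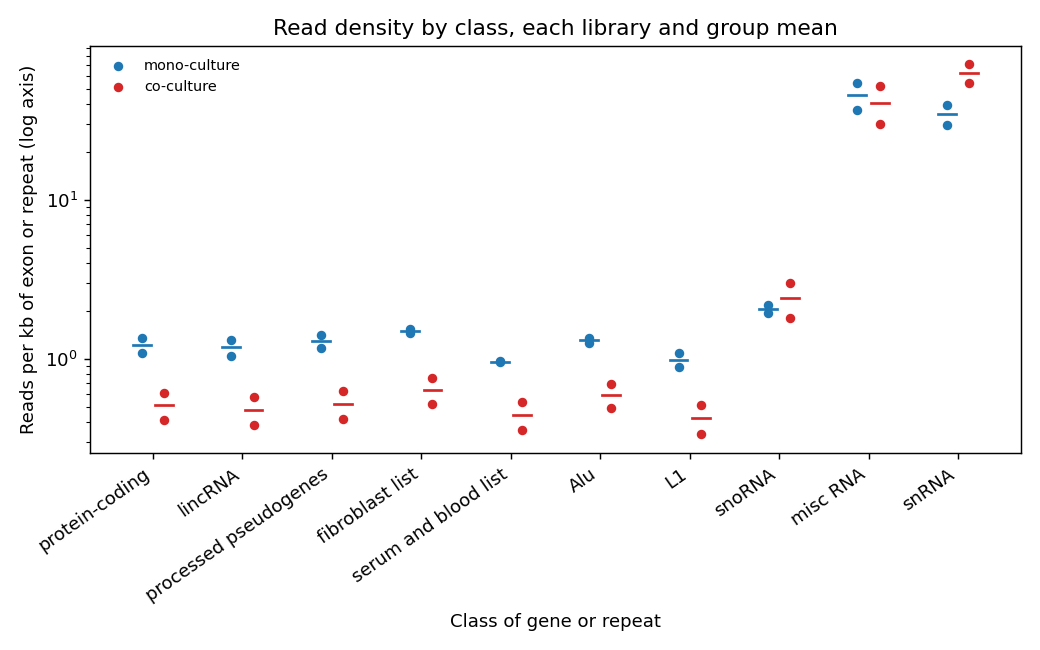
Points give reads per kb of exon or repeat (vertical log axis) in each library, not corrected for depth, for classes of genes and repeats (horizontal axis), and short lines the mean of the 2 libraries of each group. Protein-coding genes averaged 1.22 in mono-culture and 0.510 in co-culture, close to all autosomal repeats at 1.16 and 0.491, while snRNA genes averaged 34.6 and 62.6.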

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

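Scaling to rRNA, repeat counts and all assigned counts was chosen after seeing the data. RN7SL1 kept its direction under each of these and under each planned scaling and tool, with log2 fold changes from 3.36 to 6.52. With library size alone, 11 genes were higher and 7769 lower. The log2 fold change became -0.31 for SNORD3A, -0.28 for SNORD3C, -0.15 for SNORA54, -0.30 for SNORA65 and -0.68 for RNU1-3. It became -1.07 for RNU2-1, -1.24 for RNA5-8S5, -0.84 for 18S, -1.17 for RNU1-1 and -0.99 for RPH3A. For repeat families this library size also took in repeat reads, so their values are not on the scale of those of genes. SSU-rRNA_Hsa was at -0.028, with 0 families higher and 764 lower. The shift of genes follows in part from 7SL, which fills the co-culture libraries (median of all genes -3.14). Scaling to rRNA, which leaves 7SL out, still gave a median of -1.71, so 7SL is not the whole cause. Scaled to rRNA, 25 genes were higher and 5253 lower (median -1.71). Scaled to all assigned counts, 15 were higher and 7468 lower (median -2.11), with -0.030 for RNU2-1, -0.20 for RNA5-8S5 and -0.12 for RNU1-1. Scaled to repeat counts, 34 were higher and 0 lower. The replicate block, DESeq2 (where 7408 of 7798 genes had no adjusted p) and limma-voom each gave 0 genes lower, no filter 1 and at least 50 counts in 2 libraries 19, which tests 79 genes; some named genes, RPH3A among them, had too few counts for the stricter filter or no adjusted p in DESeq2, and have no value there; for the other changes of these counts the cause was not tested. Lists called were 0 higher and 0 lower with an estimated correlation, 1 higher and 0 lower with fry, and 1 higher with the stricter filter, where the cytosolic rRNA list changed direction (adjusted p = 0.983); without a filter the Y RNA pseudogene list did so (adjusted p = 0.828). Repeat families were 3 higher and 3 lower with DESeq2 size factors, 2 and 2 with DESeq2, 2 and 1 with limma-voom, 5 and 8 from loci with at least 10 counts, 0 higher with library sizes from repeats alone and 0 higher with the replicate block. With rRNA left out, 7SL held 4.21% of mono-culture and 78.0% of co-culture reads and repeats 79.7% and 17.6%; with 7SL left out repeats held 34.1% in co-culture.

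Leaving out 1 library assumes that the lone sample varies like the other group. Genes higher then ran from 0 (without mono-culture replicate 1) to 35, genes lower from 0 to 1, the log2 fold change of RN7SL1 from 6.05 to 6.77, lists lower from 0 to 2, families higher from 2 to 27 and families lower from 2 to 24. None of the named genes, the repeat family and the called lists with a value in these fits changed sign, though calls were lost in each fit. Each of these fits has 1 degree of freedom, and why 3 of them lost the RN7SL1 call was not tested. The labels do not say whether libraries with the same replicate number belong together. Deviations from the group mean of the libraries numbered 1 had a correlation of 0.00129 over 7798 genes. Most genes had few reads, so sampling noise could hide a pairing and this value cannot decide it. The block gave 39 genes higher and 0 lower. Gene counts limit what could be seen: in simulated data 14% of 2-fold changes were recovered over 7798 genes.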

Other observations

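The tests below on transcripts, olfactory receptor genes, chance between libraries, copy number, every explanation of the 7SL rise and protrusion mRNAs were chosen after the result was seen. A total of 31 protein-coding genes had reads at least 3-fold above a background set by exon length in each of the 4 libraries. With the libraries pooled, RAB13, a small GTPase, was 38.9-fold above it, TMSB10, which binds actin, 25.8-fold, GAPDH 18.9-fold (5.28 in mono-culture and 51.4 in co-culture), FTL, the ferritin light chain, 16.5-fold, USP17L13 12.4-fold, RPS12 11.1-fold, ANP32B 9.07-fold, PRR20E 8.62-fold, ACTB 8.32-fold, ELOA3B 8.32-fold, KIF1C, a kinesin motor, 6.80-fold, and TRAK2, a motor adaptor, 6.22-fold. The 31 also hold USP17L15 and USP17L17, of the same gene family as USP17L13. Reads shared between such copies may raise these ratios without mRNA. RAB13, KIF1C and TRAK2 mRNAs are known to localise to cell protrusions. A hypothesis is that such mRNAs enter these vesicles. The 8 further mRNAs of this kind that were not among the leading genes had a median ratio to background of 1.38 in mono-culture, at percentile 98.7 of 10000 random sets matched on length (random median 0.972), which is consistent with the hypothesis on a small list, but the random sets were not matched on expression.

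Ratios between small RNAs also differed. The ratio of RNY4, a Y RNA, to VTRNA1-1, a vault RNA, was 1.02 ± 0.220 in mono-culture and 0.417 ± 0.0724 in co-culture (SD, n = 2 each), and that of RNU1-1 to VTRNA1-1 was 0.267 ± 0.00746 and 0.479 ± 0.0162 (SD, n = 2 each). These ratios do not depend on scaling and were not tested. Among the 5 called protein-coding genes, VPS13A and GAPDH included, 0 shared a 25-base sequence with RN7SL1, RN7SL2 or RN7SL3. For the genes that rose, this argues against 7SL reads placed there by an exact match. Reads placed with mismatches were not examined. Of uncalled genes, 691 of 6947 shared such a sequence, so 0 among so few called genes is no difference in share.

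Protein-coding exons and repeats had similar read densities. Protein-coding exons had 1.22 reads per kb in mono-culture and repeats 1.16, and counts followed exon length (Spearman rho 0.81 across 19693 genes, which are not independent replicates). In mono-culture lincRNA genes had 1.18 reads per kb, antisense genes 1.22, processed pseudogenes 1.28 and unprocessed pseudogenes 1.20. Other sets of genes differed more: olfactory receptor genes had 0.409 reads per kb, the serum and blood list 0.958, the fibroblast list 1.5 and ribosomal protein genes 2.58. Transcripts of expressed genes and genomic DNA in the preparations cannot be told apart as the main source: the fibroblast list had 1.57 times the density of the serum and blood list but 3.67 times that of olfactory receptor genes, and repeats outside genes had 0.973 times the density of repeats antisense inside genes while olfactory receptor genes had 0.367 times that of repeats outside genes. The repeat ratio alone lay in the range set in advance for genomic DNA. The ratio of the fibroblast list to the serum and blood list lay below the bound under which transcripts were to be argued against. Both explanations stay open only because olfactory receptor genes, which were not part of these bounds, were counted as well. Their density depends on their annotated exon length. Scaling to repeat counts gave nearly the same log2 fold change for RN7SL1, 6.37. The rises of snRNA, snoRNA and 18S rRNA may in part be a higher ratio of RNA to this density in co-culture: scaled to rRNA, 9 of 9 7SL copies, 11 of 13 U1 genes or copies, 0 of 3 other snRNA genes and 1 of 5 snoRNAs stayed higher past the threshold. Scaled to all assigned counts 9 of 9 7SL copies and 3 of 13 U1 genes or copies did, and with library size alone 9 of 9 and 0 of 13, with 4 U1 genes or copies now lower.

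The ratio of repeat reads between co-culture and mono-culture varied along the genome. Over 554 autosomal bins of 5 Mb, 2 ratios that share no library had a Pearson r of 0.687 and a Spearman rho of 0.68 (permutation p = 1e-05, the smallest that the permutations can give; bins are not independent replicates), which argues against chance between libraries. The lowest bin was on chromosome 9, start 20000001, at a log2 ratio of -0.52, ranked 2 and 1 in the 2 ratios. It stayed at -0.52 after regression on GC content of transcripts, which argues against transcript GC content for this bin. GC content of the counted repeats was not used, and other bins were not examined, so GC content as a cause of the regional pattern was not decided. Copy number of 1833 DNA may explain the low ratio of this bin, since its region is deleted in MDA-MB-231. However, the lowest 1-Mb bin inside it reached -0.65 and not the -0.8 that had been set for the test. Copy number thus cannot be told apart from other causes.

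The rise of 7SL RNA was weighed against technical causes. Normalization was argued against, since the lowest log2 fold change over the scalings was 3.36. Genomic DNA reads were argued against, since background density would give 7.78e-05% of the co-culture reads, and so were reads moving between the reference sequence and its copies, which held at most 1.5% of 7SL reads in a library. Differences in RNA integrity between the libraries, which could matter as the RNA was not fragmented, were not examined. The isolation method or batch stays open: the labels of 0 of the 4 libraries name their own method. A method that differed between the cultures thus cannot be told apart from the co-culture itself, which is the biological explanation and was not tested separately. No library came from the cancer cells grown alone. RNA that the cancer cells release by themselves therefore cannot be told apart from a response of either cell type to the other. This limit holds for the other differences between the cultures as well.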
